A study of Mus musculus with 24 samples.

How the data were processed

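Liver RNA of adult male C57BL/6 mice was measured on 24 Affymetrix Mouse Gene 1.0 ST arrays, 3 at each of 8 circadian times from CT00 to CT21 in steps of 3 h. Per the labels' protocols, total RNA was taken from each liver separately, biotin labelled and hybridized to its own array, so the 3 arrays of a time are biological replicates. The labels speak of 4 mice harvested per time in one place and of 3 replicates in another, and the series text names fewer time points than the sample labels do. The grouping used here follows the sample labels.

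The deposited values were treated as log2 values. The file gives, for each of 28815 probe sets, the value of each array minus the median of that probe set over the 24 arrays, since every row median was 0 to within 5e-07. They ranged from -2.62 to 2.64, the array medians from -0.0185 to 0.0147, and the interquartile ranges of the arrays from 0.0992 to 0.200. Background correction, summarization and normalization between arrays by the authors are not given in the sources used here, and neither is the log base. Folds therefore hold for base 2. Centring removes the level of each gene, so no level of a gene is given, and brightness is known only as a class read from the rounding steps. The rounding steps left in the values put 25033 probe sets in a lower class (4 to 8) and 3780 in an upper class (8 to 16). None (0) fell in a class below 4, and 2 were undecided. A step had to fit 95% of the differences between arrays. A probe set with values on both sides of 8 therefore mostly fell in the lower class, which can hold values above 8. If a constant was added before the log was taken, changes of dim genes would be understated. Depth cannot be stated for arrays, and the number of arrays sets the precision.

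Gene symbols came from the platform annotation supplied with the data, updated through Entrez identifiers, of which 21689 were in the RefSeq table. No symbol changed (0 of 21780). Of the probe sets, 21780 had 1 symbol, 1605 had several and 5430 were not listed in that annotation and are unnamed here. Probe sets with 1 symbol were averaged per gene (998 genes had several), which gave 19935 genes. No coordinates were used. Averaging, and testing without a filter on dim genes, had been listed as alternatives. They became the main settings because the planned filter (20th percentile of the mean level, with the 50th as alternative) and the planned choice of the brightest probe set need levels that the centred values do not hold. For the same reason the eBayes trend on intensity was not run, and random lists were matched on the rounding-step class instead of deciles of the level.

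All tests used limma 3.58.1 in R 4.3.3, with empirical Bayes moderation over all genes and Benjamini-Hochberg adjustment at a threshold of 0.05. A cosine and a sine of period 24 h were fitted to the 24 arrays and tested together by a moderated F. The fit gives the amplitude (log2, from the middle of the wave to its peak), the peak time and the peak-to-trough fold, with standard errors by the delta method. Equality of the 8 time points was tested by a moderated F of the group means, and a 12 h component by the F of a second cosine and sine added to the 24 h terms. The group-mean fit also gave 4 contrasts between times 12 h apart. These contrasts use separate arrays but share the spread of all 24.

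Before the data were examined, 27 gene lists for liver and clock biology (516 members, of which 470 were tested) and 10 lists of cell type markers (95 members, of which 83 were tested) were fixed. Lists with at least 3 tested members were tested for enrichment in rhythmic genes by a one-sided Fisher exact test against all tested genes, and for a shift in each contrast by camera with a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation. In lists with at least 5 rhythmic members, the mean resultant length of the peak times (0 for scattered, 1 for equal times) was compared with 10000 random sets of rhythmic genes of the same size. The Fisher test, the matched random lists and this comparison treat genes as independent. Their p-values therefore make no allowance for members that vary together. Genes were named by a rule also fixed in advance. It took the 20 largest 24 h amplitudes, all members of both clock gene lists and the 3 smallest cosinor p in every other list. It further took the 5 largest positive and the 5 largest negative differences per contrast, the 10 largest 12 h amplitudes, and the 5 smallest p among genes that were time-dependent but not rhythmic.

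The tests were checked on simulated data of 19935 genes with the measured spread of each gene and 200 genes changed. Of 50 genes with an amplitude of 0.2 the 24 h test found 90%, the 12 h test 82% and the test of the 8 times 74%. At an amplitude of 0.1 the shares were 46%, 42% and 14%. A difference of 0.4 between CT12 and CT00 was found for 72% of 50 genes, and one of 0.8 for 92%. Unchanged genes gave 8 false calls among 174 in the 24 h test and 6 among 167 in the 12 h test. In the test of the 8 times they gave 3 among 144, and in CT12 against CT00 9 among 148. The noise was drawn independently for each gene and array, so spread shared by many genes was not simulated.

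Alternatives set in advance were quantile normalization, centring of each array on its median, ordinary tests without moderation, array weights, the replicate number as a block, a minimum of 1.5-fold, within-gene ranks, a period of 23 h, the spread of the 6 arrays of a contrast alone, and fits without each array and each time point. Alternatives chosen after seeing the data were a robust prior, brighter probe sets only, each probe set on its own, the mean small nucleolar RNA value of an array as a covariate, and a fit without the 4 arrays farthest from the mean of their time point (CT09 replicate 3, CT15 replicates 1 and 2, CT18 replicate 3). Matching random lists on the rounding-step class, in place of deciles of the level, was also chosen then. The 24 arrays of the deposited table were all used.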

Results

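Transcript levels were measured in livers of adult male C57BL/6 mice held in constant dim red light with free access to food, after entrainment to a cycle of light and dim red light. Livers were collected on the second cycle after the change to constant conditions, so that the remaining rhythm came without a light cycle. By convention, which the labels do not spell out, circadian time (CT) counts hours from the former onset of light: CT00 to CT12 is the subjective day and CT12 to CT24 the subjective night, when mice are active. Each of 8 times, 3 h apart, had 3 arrays from separate livers (24 arrays), and 19935 genes were tested. Values are relative to the median of each gene over all arrays, and folds assume that the deposited log values have base 2.

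The comparison over the whole cycle asked which transcripts follow a 24 h wave in constant conditions. The sampled times did not extend into another cycle, so whether a wave recurs was not observed. Rhythmic here means called in this 24 h fit. The widest swings included those of clock genes and of genes of lipid metabolism and signalling. Nr1d1, which encodes the nuclear receptor REV-ERB alpha, led with a peak-to-trough fold of 10.3 (amplitude 1.68 ± 0.13, SE) and a peak at 7.29 h ± 0.29. Dbp, a PAR bZIP transcription factor, followed with 7.73-fold and a peak at 10.1 h, and Elovl3, an elongase of very long fatty acids, with 6.93-fold and a peak at 0.211 h. Ciart (5.86-fold, peak at 11.3 h), Rgs16, a regulator of G protein signalling (5.81-fold, 9.26 h), and Arntl, which encodes BMAL1 (5.20-fold, 22.7 h), came next. In all, 2758 of the 19935 genes (13.8%) were rhythmic by limma's moderated F at an adjusted p under 0.05. The median fold of these was 1.26 and the 90th percentile 1.62, 423 reached 1.5-fold and 99 reached 2-fold.

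Of the 13 tested genes of the negative limb of the clock and the PAR bZIP factors, all 13 were rhythmic (adjusted p of the Fisher test for enrichment 1.69e-10), and 13 were with p adjusted over the list alone. Their peaks ran from the subjective day into the night: Nr1d1 at 7.29 h, Bhlhe41 at 9.21 h, Nr1d2 at 9.99 h, Dbp at 10.1 h, Ciart at 11.3 h, Tef and Per3 at 12.0 h, Per1 at 12.2 h, Cry2 at 12.4 h, Hlf at 13.0 h, Bhlhe40 at 13.9 h, Per2 at 15.2 h and Cry1 at 20 h. Their mean peak was at 11.9 h, and the peaks were closer together than in random sets of rhythmic genes (resultant length 0.753, adjusted p = 0.0051). In the list of positive limb genes and genes controlled through ROR elements, 3 of 5 were rhythmic (adjusted p of the enrichment 0.0346). Their fitted peaks lay late in the night: Arntl at 22.7 h, Clock at 23.5 h with 1.84-fold, and Nfil3 at 22.4 h. The group means of these 3, in that order, were highest at CT00, the start of the subjective day (0.763, 0.329 and 0.433). Those at CT03 (0.715, 0.254 and 0.413) also lay above those at CT21 (0.625, 0.181 and 0.207). Arntl2 (adjusted p = 0.474) and Rora (adjusted p = 0.166) did not pass, and 4 of the 5 passed with the p adjusted over the list alone. Among 13 modifiers of clock proteins only Usp2 (4.09-fold, 13.0 h), Ddb1 and Btrc passed, and the list was not enriched (adjusted p = 0.327; 3 adjusted over the list alone). At CT00 the 3 arrays differed widely for Nr1d1 (-0.89 ± 0.77, SD, n = 3), Dbp (-0.88 ± 0.97, SD, n = 3) and Ciart (-0.47 ± 0.71, SD, n = 3). The Bhlhe40 call was lost without CT03 (adjusted p = 0.0988), that of Btrc without CT06 (0.0678) or CT15 (0.0695), and the enrichment of the smaller list with random lists matched on brightness class (adjusted p = 0.0574).

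**Figure D1:**
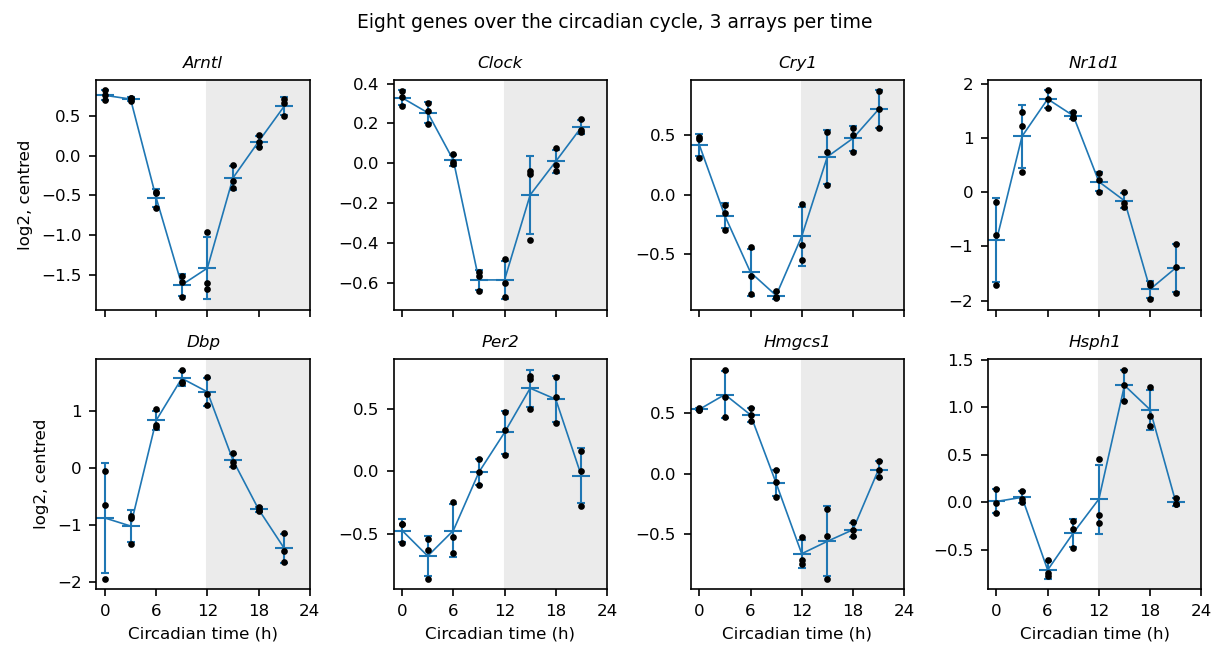
Centred log2 values of 8 genes (vertical axes) against circadian time in hours. Points are single arrays, horizontal bars and error bars the mean and SD of 3 arrays, and grey marks the subjective night. Arntl was highest at CT00 (mean 0.76) and lowest at CT09 (mean -1.63), while Nr1d1 was highest at CT06 (mean 1.72) and lowest at CT18 (mean -1.79).

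Lipid genes made up several of the enriched lists. Of 22 cholesterol synthesis and uptake genes, 17 were rhythmic (adjusted p = 2.72e-10; 20 adjusted over the list alone), 13 of them with a day peak, and their peaks were concentrated around 1.68 h (resultant length 0.814, adjusted p = 0.00085). Hmgcs1, which makes the precursor of mevalonate, had 2.59-fold with a peak at 2.60 h, Insig2, which retains the SREBP complex in the endoplasmic reticulum, 2.88-fold at 0.678 h, and Fdft1, squalene synthase, 1.56-fold at 2.27 h. Of 18 bile acid genes, 12 were rhythmic (adjusted p = 2.06e-06; 13 adjusted over the list alone), with Hsd3b7, a bile acid synthesis enzyme, at 2.88 h (2.06-fold), the export pump gene Abcb11 at 2.87 h (1.5-fold) and the sterol exporter gene Abcg8 at 9.06 h (2.36-fold). Fatty acid and triglyceride synthesis had 17 of 25 rhythmic members (adjusted p = 5.52e-09; 18 adjusted over the list alone), whose peaks were not closer together than chance (adjusted p = 0.937). Thrsp, a lipogenic regulator, peaked at 16.1 h (2.59-fold) and Elovl3 at 0.211 h, while Pnpla2, which breaks triglycerides down and is in this list, peaked at 9.30 h (1.65-fold). Of 23 fatty acid oxidation genes 9 were rhythmic (adjusted p = 0.00518; 10 adjusted over the list alone), among them Cpt1a at 9.62 h (1.95-fold), Ppara at 9.86 h (1.71-fold) and Pdk4, an inhibitor of pyruvate oxidation, at 23.9 h (2.71-fold). The enrichment of this last list was lost against lists matched on brightness class (adjusted p = 0.215).

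Carbohydrate and amino acid genes followed. In glycolysis and glycogen metabolism 9 of 13 were rhythmic (adjusted p = 3.35e-05; 12 adjusted over the list alone), including the glycogen synthase gene Gys2 (2.12-fold, 12.9 h), the glycogen targeting subunit gene Ppp1r3c (3.41-fold, 23.6 h) and the glucose transporter gene Slc2a2 (1.55-fold, 10.9 h). In gluconeogenesis and amino acid catabolism 11 of 20 were rhythmic (adjusted p = 6.49e-05; 13 adjusted over the list alone), with peaks around 11.7 h (resultant length 0.687, adjusted p = 0.0272). Pck1, the gluconeogenic enzyme, had 3.32-fold at 9.87 h, Slc37a4 1.89-fold at 14.2 h, Asl 1.56-fold at 16.8 h and Hal 1.61-fold at 2.54 h. Of 12 glucocorticoid-responsive genes 5 were rhythmic (adjusted p = 0.0298; 5 adjusted over the list alone): Fkbp5 peaked at 14.4 h (2.68-fold), Tsc22d3 at 16.3 h (1.83-fold) and the metallothionein gene Mt1 at 9.14 h (3.31-fold). Nampt, the NAD salvage enzyme, peaked at 14.1 h (2.60-fold), and Nnmt and Nadsyn1 were rhythmic too, in a list with 6 of 15 called (adjusted p = 0.0212; 11 adjusted over the list alone). Against random lists matched on brightness class the enrichment was lost for gluconeogenesis (adjusted p = 0.0574), glucocorticoid-responsive genes (adjusted p = 0.0813) and NAD metabolism (adjusted p = 0.0917). Without the 4 farthest arrays the glucocorticoid list was not enriched either (adjusted p = 0.0659).

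Heat shock chaperones peaked together in the subjective night. Of 17 members 15 were rhythmic (adjusted p = 1.69e-10; 15 adjusted over the list alone), all 15 with a night peak, and their mean peak was at 17.4 h (resultant length 0.915, adjusted p = 0.00085). Hsp90aa1 had 2.22-fold at 18.9 h, Hspa4l 1.99-fold at 18.9 h, and the small heat shock protein gene Hspb1 2.34-fold at 20.1 h. Among 24 chaperones of the endoplasmic reticulum and genes of the unfolded protein response 12 were rhythmic (adjusted p = 8.34e-05; 19 adjusted over the list alone), and their peaks did not pass the test for concentration (adjusted p = 0.13). Herpud1, of the degradation pathway, peaked at 12.0 h, Trib3 at 6.63 h and Calr at 23.5 h. Both cold-inducible RNA-binding protein genes were rhythmic, Cirbp at 5.61 h (1.60-fold) and Rbm3 at 12.1 h (1.58-fold). Ribosome biogenesis had 11 of 23 rhythmic members (adjusted p = 0.000223; 17 adjusted over the list alone) around 15.3 h (resultant length 0.757, adjusted p = 0.011), with Nolc1 at 16.9 h, Nop56 at 15.9 h and Rrp12 at 17.3 h. In contrast, 0 of 18 ribosomal protein genes were called by limma, and 0 with p adjusted over the list alone. The 3 with the smallest p were Rps20, Rpl10a and Rps18 (adjusted p = 0.205, 0.216 and 0.263), of which Rps20 had an unadjusted p of 0.0485 and an adjusted p of 0.0488 without CT00. Without the 4 farthest arrays 6 ribosome biogenesis genes were called and the list was not enriched (adjusted p = 0.0659). Nor was it among brighter probe sets alone, with 2 called (adjusted p = 0.706).

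Further enriched lists were autophagy and lysosome with 10 of 19 (adjusted p = 0.000204; Gabarapl1 at 6.59 h, the autophagy kinase gene Ulk1 at 8.96 h, Bnip3 at 12.8 h), xenobiotic metabolism with 11 of 23 (adjusted p = 0.000223; Gstt2 at 8.99 h, the nuclear receptor gene Nr1i3 at 10.5 h, Abcb1a at 12.3 h), the growth hormone axis with 7 of 16 (adjusted p = 0.007; Stat5b at 2.36 h, Igfbp4 at 13.1 h, Stat5a at 3.08 h) and the acute phase response with 6 of 18 (adjusted p = 0.0449; Apcs at 3.97 h, Steap4 at 14.2 h, Saa4 at 15.1 h). Counts adjusted over the list alone were 10, 13, 8 and 6. Against lists matched on brightness class the xenobiotic (adjusted p = 0.0641), growth hormone (adjusted p = 0.0766) and acute phase (adjusted p = 0.358) lists were not enriched, and the acute phase call was also lost without any of CT00 replicate 3 (adjusted p = 0.149), CT09 replicates 1, 2 or 3 (0.121, 0.145 and 0.0988), CT12 replicate 1 (0.0981), CT18 replicate 3 (0.109) or CT21 replicate 2 (0.109). It was lost as well without CT00 (0.153), CT03 (0.0591), CT06 (0.0521), CT09 (0.138), CT12 (0.131), CT15 (0.0876) or CT21 (0.0856), with array weights (0.181), without moderation (0.0954), with the small nucleolar RNA covariate (0.0635) and without the 4 farthest arrays (0.195). The growth hormone call was lost without CT03 (adjusted p = 0.12), CT09 (0.106), CT18 (0.127) or CT21 (0.0567), and without the 4 farthest arrays (0.0537), where Stat5a was not called either (0.054).

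Cell cycle genes were not enriched (5 of 22, adjusted p = 0.243; 6 adjusted over the list alone), but were with a minimum of 1.5-fold (3 members, adjusted p = 0.0201). The 5 rhythmic members still peaked close together, around 12.6 h (resultant length 0.927, adjusted p = 0.0224), with the kinase gene Wee1 at 13.0 h (3.53-fold), the ribonucleotide reductase gene Rrm2 at 13.5 h and the cyclin gene Ccne1 at 11.4 h. Immediate early genes (4 of 16, adjusted p = 0.243; Egr1, Gadd45a and Zfp36), heme and iron metabolism (3 of 18, adjusted p = 0.523; Alas1, the regulated enzyme of heme synthesis, with 3.45-fold at 13.8 h, Uros and Fech), the respiratory chain (3 of 22, adjusted p = 0.654; Cox5a, Cyc1 and Ndufv2), proteasome subunits (3 of 25, adjusted p = 0.72; Psmd11, Psma5 and Psmc2) and abundant secreted proteins (3 of 17, adjusted p = 0.502; the fibrinogen genes Fgg, Fga and Fgb) were not enriched. Their counts adjusted over the list alone were 6, 5, 3, 3 and 3. With the mean small nucleolar RNA value of an array as a covariate, 8 proteasome genes were rhythmic and their list was enriched (adjusted p = 0.042). Of 11 reference genes often used for normalization, 3 were rhythmic (adjusted p = 0.243; 3 adjusted over the list alone): Gusb at 17.6 h with 1.27-fold, Actb at 23.8 h with 1.21-fold and Pgk1 at 18.3 h with 1.14-fold. The Pgk1 call was lost without CT06 replicates 1 or 2 (adjusted p = 0.0631 and 0.0623) or CT18 replicates 2 or 3 (0.0543 and 0.0538), that of Ndufv2 without CT09 replicate 3 (0.0514) or CT18 replicates 2 or 3 (0.0632 and 0.0638), and that of Fech without CT12 replicate 1 (0.0516). Calls were also lost without whole time points: Egr1 without CT03 (0.092), Gadd45a without CT21 (0.0993), Zfp36 without CT06, CT18 or CT21 (0.0871, 0.078 and 0.0821), Psmc2 without CT03 or CT18 (0.0697 and 0.0677) and Cyc1 without CT18 (0.0669). Pgk1 lost the call without CT06, CT09, CT15, CT18 or CT21 (0.0962, 0.0623, 0.0523, 0.0784 and 0.0573), Fech without CT03, CT12, CT15 or CT21 (0.0505, 0.231, 0.0624 and 0.0943), and Ndufv2 without CT03, CT09, CT12, CT15 or CT18 (0.0655, 0.105, 0.0501, 0.0582 and 0.137). Without the 4 farthest arrays Ndufv2 (0.196), Fech (0.0931) and Pgk1 (0.0648) lost it as well. The brightness classes were coarse, with 25033 probe sets in the lower and 3780 in the upper, so levels within a class were not matched. In total 17 of 26 lists were enriched, 9 of them also against lists matched on brightness class. Of these 9, the bile acid (adjusted p = 0.07), autophagy (0.1585) and ribosome biogenesis lists (0.706) were not enriched among brighter probe sets alone. The negative limb and PAR bZIP list had too few members there to be tested. With a minimum of 1.5-fold ribosome biogenesis (adjusted p = 0.122), NAD metabolism (0.0639) and the acute phase response (0.379) were not. Of 17 lists with enough rhythmic members, 6 had concentrated peaks.

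None of the 10 lists of markers for other cell types was enriched (0 of 10 at an adjusted p under 0.05, limma and Fisher's exact test, and 0 at an unadjusted p under 0.05). No marker of Kupffer cells, lymphocytes, neutrophils, endothelial cells, exocrine pancreas, red blood cells or muscle was called in the 24 h fit, while the test of equality over the 8 times called 1 neutrophil and 1 endothelial marker. The stellate cell, bile duct and adipocyte lists had 1 rhythmic member each, as they had with p adjusted over the list alone. These were Pdgfrb, Sox9 and Car3, which were looked up after the counts were seen.

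**Figure D2:**
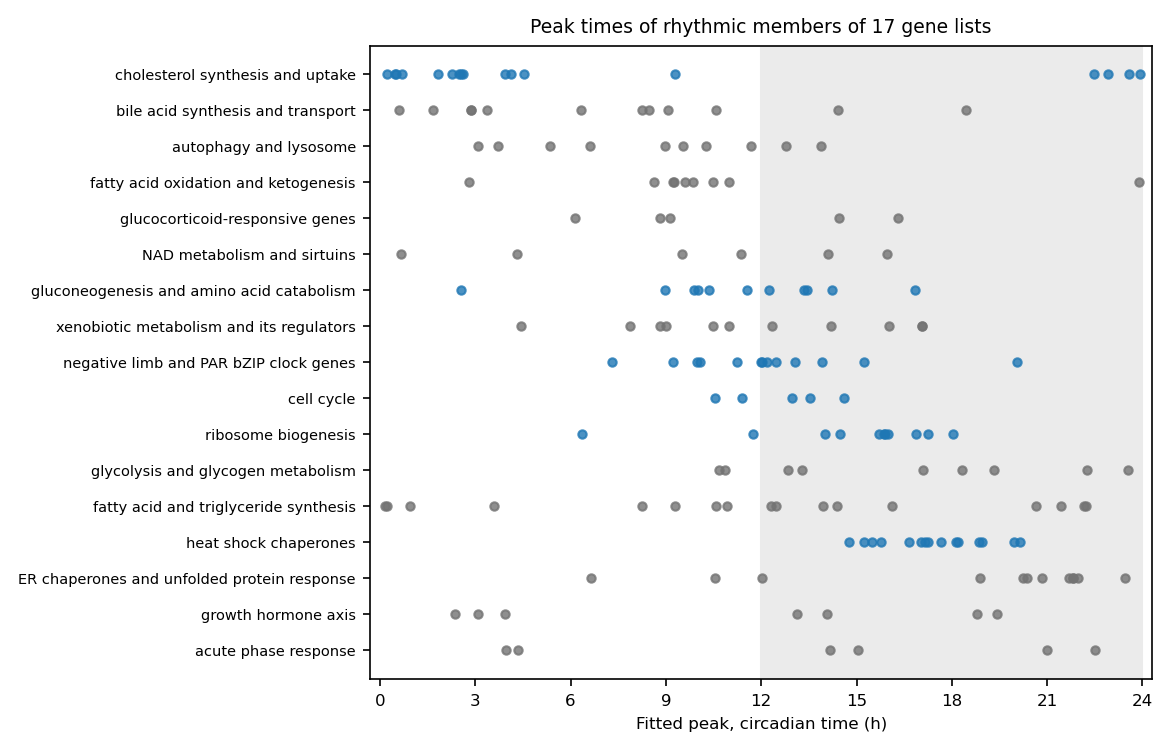
Fitted peak times in hours (horizontal axis) of the rhythmic members of 17 gene lists (vertical axis). Each point is a gene, blue lists have peaks closer together than random sets of rhythmic genes at an adjusted p under 0.05, grey lists do not, and the shaded part is the subjective night. The 15 heat shock chaperones all lie in the shaded part, around 17.4 h, and the cholesterol genes around 1.68 h.

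Rhythmic genes peaked at every time of the cycle. Of the 2758, 1598 peaked in the subjective day and 1160 in the subjective night (42.1%, exact 95% binomial interval 40.2 to 43.9, which treats genes as independent and covers counting error only). The fullest 3 h bin was 6 to 9 h with 490 genes and the emptiest 18 to 21 h with 219. Among the 423 genes with at least 1.5-fold, 220 peaked at night (52.0%, interval 47.1 to 56.9). The share among all rhythmic genes was 51.1% when a gene was placed by the time of its highest group mean. It ranged from 39.0% without CT09 replicate 2 to 46.0% without CT21 replicate 3, and from 37.4% to 48.9% when whole time points were left out.

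**Figure D3:**
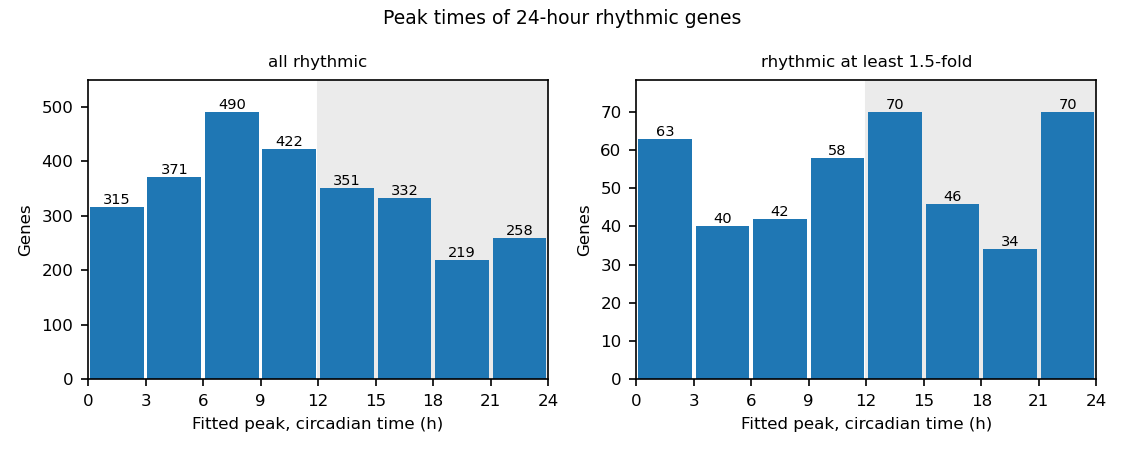
Number of 24 h rhythmic genes (vertical axes) by fitted peak time in 3 h bins (horizontal axes), for all 2758 genes on the left and for the 423 with at least 1.5-fold on the right. Grey marks the subjective night, in which 1160 and 220 of the genes peaked.

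The test of equality over the 8 times, which allows any shape, called 2167 genes (4994 at an unadjusted p under 0.05), of which 1726 were also 24 h rhythmic and 441 were not. Among those 441, Dnajc18 and Gmps, which encodes GMP synthetase, were highest at CT15 (0.51 ± 0.11 and 0.28 ± 0.13, SD, n = 3), as was the chaperone gene Dnajb9 (0.67 ± 0.33, SD, n = 3). The sphingosine kinase gene Sphk2 was highest at CT03 (0.49 ± 0.06, SD, n = 3), and Csad, an enzyme of taurine synthesis, was lowest at CT18 (-0.65 ± 0.03, SD, n = 3). With array weights the test called 4900 genes.

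A 12 h component was found in 115 genes, 64 of them also 24 h rhythmic. Among these 115, the largest 12 h amplitudes were those of Ciart (0.49 ± 0.08, SE), the heat shock gene Hsph1 (0.40 ± 0.07, SE), Usp2 (0.39 ± 0.05, SE), Arntl (0.37 ± 0.05, SE), Pdk4 (0.34 ± 0.06, SE), the tight junction gene Cldn1 (0.31 ± 0.04, SE), the collagen prolyl hydroxylase gene P4ha1 (0.31 ± 0.05, SE), Hspa13 (0.31 ± 0.06, SE), Bhlhe41 (0.30 ± 0.05, SE) and Chordc1 (0.30 ± 0.06, SE). Hsph1 stood at 1.23 ± 0.16 (SD, n = 3) at CT15 and -0.71 ± 0.09 (SD, n = 3) at CT06. Its means at CT09 and CT18 were -0.32 ± 0.15 and 0.97 ± 0.21 (SD, n = 3), and at CT12 the arrays scattered around 0.03 with an SD of 0.36. Heat shock chaperones held 6 of the 115 genes. With quantile normalization 64 genes were called and the calls of Hsph1 (adjusted p = 0.0817), Pdk4 (0.0786), P4ha1 (0.079), Hspa13 (0.0746) and Chordc1 (0.0641) were lost. Without moderation Ciart (adjusted p = 0.0604), P4ha1 (0.0601), Pdk4 (0.091), Hspa13 (0.097) and Chordc1 (0.0917) lost the call, and without the 4 farthest arrays Hsph1 (0.0951), Pdk4 (0.0723), P4ha1 (0.12) and Bhlhe41 (0.0585). The count was 61 and 63 without CT00 replicates 2 and 3, 76 without CT03 replicate 2, 183 without CT06 replicate 3, 74 and 66 without CT09 replicates 1 and 2, 188, 47 and 69 without CT15 replicates 1, 2 and 3, and 75 and 48 without CT21 replicates 2 and 3. The P4ha1 call was lost without CT15 replicate 2 (adjusted p = 0.0581) or CT21 replicate 3 (0.0564). The Pdk4 call was lost without CT00 replicate 2 (0.0559), CT03 replicates 1 or 2 (0.0791 and 0.0702), CT09 replicates 1 or 2 (0.0719 and 0.0632), CT15 replicates 2 or 3 (0.0898 and 0.0598) or CT21 replicates 1 or 3 (0.0541 and 0.0948). The Chordc1 call was lost without CT00 replicates 2 or 3 (0.0565 and 0.0520), CT03 replicate 2 (0.0573), CT06 replicate 2 (0.0516), CT09 replicates 1 or 2 (0.0735 and 0.0781), CT15 replicates 2 or 3 (0.0995 and 0.0649) or CT21 replicates 1, 2 or 3 (0.0532, 0.0787 and 0.0998). The Hspa13 call was lost without any array of CT00 (0.0528, 0.0587 and 0.0565) or CT03 (0.0723, 0.0515 and 0.0710), CT09 replicates 1 or 2 (0.0735 and 0.0511), CT12 replicate 3 (0.0528), CT15 replicates 2 or 3 (0.108 and 0.0769) or CT21 replicates 1 or 3 (0.0655 and 0.110).

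**Figure D4:**
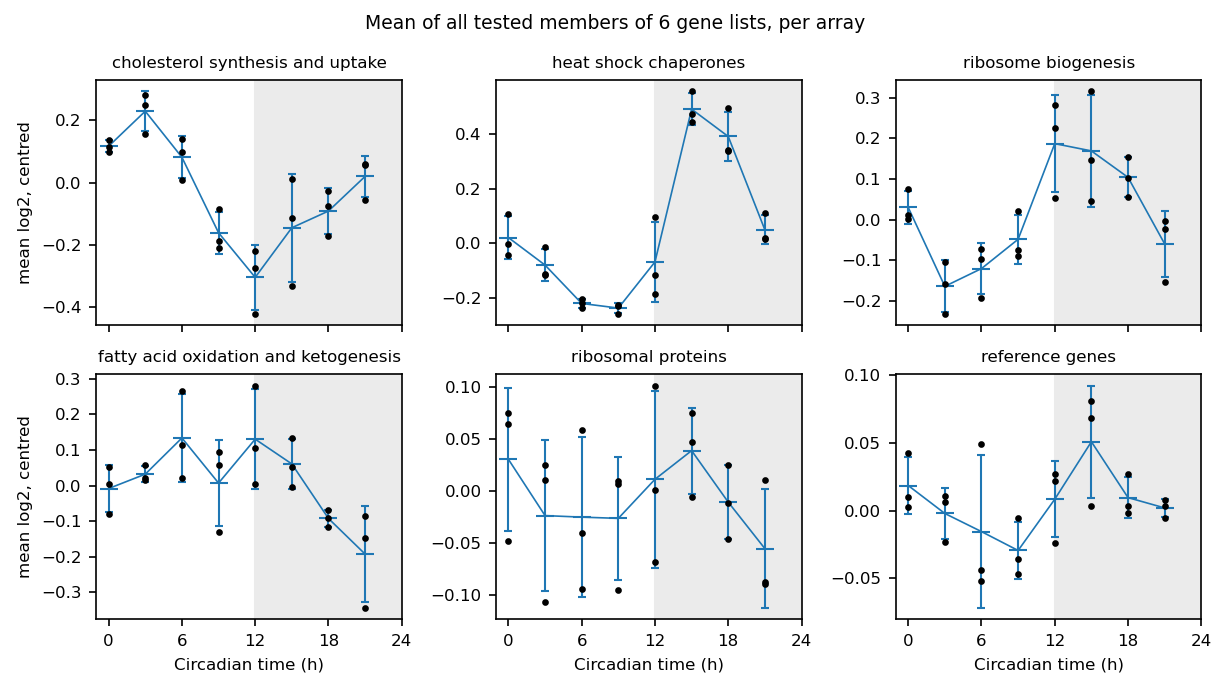
Mean centred log2 value over all tested members of 6 gene lists (vertical axes) against circadian time in hours. Points are single arrays, horizontal bars and error bars the mean and SD of 3 arrays, and grey marks the subjective night. Heat shock chaperones had their highest mean at CT15 (0.49 ± 0.06) and the cholesterol list at CT03 (0.23 ± 0.06).

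Between CT12, the start of the subjective night, and CT00, the start of the subjective day, 690 genes differed. At CT12, 357 were higher and 333 lower. Mfsd2a, a lysophospholipid transporter gene, was higher by 2.42 ± 0.36 (SE, log2), Lpin1, a phosphatidate phosphatase gene, by 2.37 ± 0.24, Dbp by 2.22 ± 0.29, Ciart by 2.16 ± 0.23 and Rgs16 by 1.98 ± 0.34. Elovl3 fell by 2.92 ± 0.17, Arntl by 2.18 ± 0.13, Ppp1r3c by 2.08 ± 0.25, the water channel gene Aqp8 by 2.05 ± 0.14 and the choline kinase gene Chka by 1.99 ± 0.16. As a list, the negative limb and PAR bZIP genes were higher at CT12 (camera adjusted p = 3.04e-23, 11 members called higher and 1 lower), as were glucocorticoid-responsive genes (adjusted p = 5e-06, 2 called higher) and cell cycle genes (adjusted p = 0.000319, 4 called higher). Positive limb genes (adjusted p = 1.59e-10, 3 lower) and cholesterol genes (adjusted p = 1.96e-17, 11 lower) were lower. With an estimated correlation these calls held, at adjusted p = 0.000738, 0.0079, 0.0458, 0.000192 and 0.0216. Gluconeogenesis genes (7 higher, 1 lower, adjusted p = 1.82e-08) lost the call at an adjusted p of 0.0556 with an estimated correlation. So did xenobiotic (4 higher, adjusted p = 0.00132, 0.334 with an estimated correlation), ribosome biogenesis (0 called, 0.00415, then 0.339) and glycolysis genes (4 higher, 1 lower, 0.0422, then 0.383), which were higher. Chaperones of the endoplasmic reticulum (1 higher, 2 lower, 0.000154, then 0.376) and secreted proteins (2 lower, 0.0084, then 0.339) were lower. The glycolysis call was lost without CT00 replicate 1 (adjusted p = 0.0564), CT09 replicates 2 or 3 (0.0553 and 0.0648), or CT12 replicates 1 or 2 (0.0541 and 0.139), and that of ribosome biogenesis without CT12 replicate 2 (0.124). The glycolysis call was also lost with quantile normalization (0.118) and without the 4 farthest arrays (0.0591). Among brighter probe sets alone the glucocorticoid-responsive (adjusted p = 0.357), glycolysis (0.444), ribosome biogenesis (0.228), xenobiotic (0.357) and secreted protein lists (0.0813) lost their calls. The bile duct marker list was lower at CT12 (mean difference -0.22, 1 of 7 called, camera adjusted p = 0.00193, adjusted p = 0.184 with an estimated correlation). The count was 400 and 422 without CT00 replicates 1 and 2, 437 without CT12 replicate 3, and 1388 with array weights.

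At CT15 against CT03, 535 genes were higher and 359 lower. Ciart was higher by 1.78 ± 0.23 (SE, log2), Nrg4, a neuregulin gene, by 1.78 ± 0.15, Mfsd2a by 1.74 ± 0.36, Usp2 by 1.71 ± 0.13 and Wee1 by 1.69 ± 0.17. Aqp8 fell by 1.94 ± 0.14, Elovl3 by 1.75 ± 0.17, the ubiquitin ligase gene Rnf125 by 1.75 ± 0.14, Depp1 by 1.48 ± 0.29 and Igfbp1 by 1.42 ± 0.29. Heat shock chaperones were higher (12 of 17 called, camera adjusted p = 4.70e-20), as were ribosome biogenesis genes (10 of 23 called, adjusted p = 1.16e-11). With an estimated correlation the adjusted p were 0.00323 and 0.0332. Cholesterol genes were lower (9 of 22 called, adjusted p = 1.64e-12), at an adjusted p of 0.0542 with an estimated correlation. Negative limb genes were higher (9 higher, 1 lower, adjusted p = 7.12e-16) and positive limb genes lower (2 lower, 0.000111), at adjusted p of 0.00333 and 0.00632 with an estimated correlation. Cell cycle (4 higher, adjusted p = 0.000507, 0.0526 with an estimated correlation), glucocorticoid-responsive (2 higher, 0.00145, then 0.0556), gluconeogenesis (3 higher, 1 lower, 0.00228, then 0.334), glycolysis (2 higher, 0.00422, then 0.26), xenobiotic (4 higher, 1 lower, 0.0175, then 0.45) and heme genes (1 higher, 0.0408, then 0.215) were also higher. Ribosomal protein genes (mean difference 0.06, adjusted p = 0.0202) and respiratory chain genes (mean difference 0.06, adjusted p = 0.0169) were higher with 0 called members, at adjusted p of 0.339 and 0.154 with an estimated correlation. The mean of 54 small nucleolar RNA genes was 0.08 ± 0.11 (SD, n = 3) at CT15 and -0.09 ± 0.10 (SD, n = 3) at CT03, and with it as a covariate the calls of these lists were lost (adjusted p = 0.506 and 0.225). The difference of the list mean went from 0.063 ± 0.053 (SE) to 0.0036 ± 0.047 for ribosomal proteins and from 0.061 ± 0.023 to 0.036 ± 0.021 for the respiratory chain. Heme (adjusted p = 0.13) and xenobiotic genes (0.0535) lost the call too, while their differences went from 0.19 ± 0.05 to 0.20 ± 0.06 and from 0.10 ± 0.05 to 0.11 ± 0.06. The ribosomal protein call was also lost without CT03 replicate 3 (0.203) or CT15 replicate 1 (0.0711), that of gluconeogenesis without CT15 replicate 1 (0.11), that of heme genes without CT03 replicates 1 or 2 (0.0558 and 0.12) or CT15 replicate 2 (0.196), and that of xenobiotic genes without CT03 replicate 1 (0.107) or CT15 replicate 2 (0.0881). Without the 4 farthest arrays the ribosomal protein (0.0579), heme (0.235) and xenobiotic (0.0543) calls were lost, and with quantile normalization that of heme genes (0.0854). Among brighter probe sets alone the glycolysis (0.532), gluconeogenesis (0.322), glucocorticoid-responsive (0.944), ribosomal protein (0.358), respiratory chain (0.388), heme (0.358) and xenobiotic lists (0.285) lost their calls. The total of 894 genes was 535 without CT03 replicate 1, 353 with the spread of these 6 arrays alone, and 440 without the 4 farthest arrays, where the calls of Mfsd2a and Depp1 were lost (adjusted p = 0.187 and 0.0525). The Igfbp1 call was lost with the spread of the 6 arrays (adjusted p = 0.112).

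At CT18 against CT06, fewer genes were higher (286) than lower (639). The largest rise was that of Hsph1, by 1.69 ± 0.13 (SE, log2), followed by Nat8f5 (1.63 ± 0.23), Thrsp (1.33 ± 0.15), the calcineurin regulator gene Rcan1 (1.25 ± 0.18) and Creld2 (1.20 ± 0.28). Nr1d1 fell by 3.51 ± 0.29, Dbp by 1.57 ± 0.29, Pck1 by 1.54 ± 0.36, the peroxisomal transporter gene Abcd2 by 1.5 ± 0.31 and BC023105 by 1.43 ± 0.33. Heat shock chaperones were higher as a list (13 of 17 called, camera adjusted p = 1.03e-20, 0.00323 with an estimated correlation). Proteasome subunits (2 of 25 called, adjusted p = 1.38e-06), bile acid genes (6 lower and 1 higher of 18, adjusted p = 6.51e-06) and fatty acid oxidation genes (4 of 23 lower, adjusted p = 0.000135) were lower. With an estimated correlation their adjusted p were 0.135, 0.154 and 0.215. Autophagy (4 lower, adjusted p = 0.000277, 0.0918 with an estimated correlation), cholesterol (5 lower, 0.000674, then 0.339) and secreted protein genes (0 called, 0.00216, then 0.295) were lower too. Chaperones of the endoplasmic reticulum (7 higher, 1 lower, 3.61e-07, then 0.26), ribosome biogenesis (3 higher, 8.29e-05, then 0.215) and glycolysis genes (3 higher, 1 lower, 0.0181, then 0.339) were higher. The glycolysis call was lost without CT06 replicate 2 (0.179) or CT18 replicate 3 (0.128), and without the 4 farthest arrays (0.0839). Among brighter probe sets alone the bile acid (0.159), fatty acid oxidation (0.145), glycolysis (0.296), ribosome biogenesis (0.839), secreted protein (0.333) and autophagy lists (0.0781) lost their calls. The total of 925 genes was 501 without CT06 replicate 3, 475 without CT18 replicate 2 and 367 with the spread of these 6 arrays alone. The Pck1 call was lost without CT06 replicate 1 (adjusted p = 0.0591) or CT18 replicate 2 (0.0762), that of BC023105 without CT06 replicate 1 (0.0743) or CT18 replicate 1 (0.058), and that of Creld2 without CT06 replicate 3 (0.065), CT18 replicate 1 (0.0527) or CT18 replicate 3 (0.0627).

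At CT21 against CT09, 311 genes were higher and 398 lower. Arntl was higher by 2.26 ± 0.13 (SE, log2), Elovl3 by 2.02 ± 0.17, Nat8f5 by 1.77 ± 0.23, the aromatic amino acid decarboxylase gene Ddc by 1.74 ± 0.20 and Chka by 1.72 ± 0.16. Dbp fell by 2.99 ± 0.29, Nr1d1 by 2.81 ± 0.29, Rgs16 by 2.68 ± 0.34, Ciart by 2.25 ± 0.23 and Nr1d2 by 2.05 ± 0.25. Positive limb genes were higher (3 of 5 called, camera adjusted p = 1.16e-11) and negative limb and PAR bZIP genes lower (8 lower and 1 higher of 13, adjusted p = 6.39e-15), at adjusted p of 0.000192 and 0.00398 with an estimated correlation. Heat shock chaperones were higher (5 higher and 1 lower of 17, adjusted p = 4.47e-06), at an adjusted p of 0.119 with an estimated correlation. Cholesterol (5 higher, adjusted p = 0.000241, 0.334 with an estimated correlation) and respiratory chain genes (0 called, 0.0299, then 0.214) were higher. Fatty acid oxidation (1 higher, 4 lower, 0.000319, then 0.253), autophagy (3 lower, 0.00117, then 0.136), proteasome (1 lower, 0.00227, then 0.339) and cell cycle genes (4 lower, 0.0106, then 0.154) were lower. Without CT21 replicate 3 these 4 lost the call (0.0593, 0.0664, 0.133 and 0.0624), as did cell cycle genes without CT09 replicate 1 (0.0591) and the respiratory chain without CT09 replicates 2 or 3 (0.0578 and 0.126) or CT21 replicate 1 (0.284). The respiratory chain call was also lost with the small nucleolar RNA covariate (adjusted p = 0.0795), with a difference of the list mean of 0.056 ± 0.023 (SE) before and 0.049 ± 0.019 after, and it was lost without the 4 farthest arrays (0.145). Among brighter probe sets alone the cholesterol (0.216), respiratory chain (0.22), proteasome (0.116) and autophagy lists (0.296) lost their calls. Without CT21 replicate 3, 56.4% of the called genes were higher at CT21 instead of 43.9%, and the total of 709 was 420. Without CT21 replicate 2 it was 441, with the spread of these 6 arrays alone 300, and with array weights 1211. The share was 55.0% without the 4 farthest arrays.

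Over the 4 contrasts 43 of 104 list tests passed, 12 with an estimated correlation. Of the genes called in a contrast, 96.5% (CT12 against CT00), 88.4% (CT15 against CT03), 88.4% (CT18 against CT06) and 92.4% (CT21 against CT09) were also 24 h rhythmic. In all 4 contrasts 30 genes were called.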

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

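Probe sets that name no single gene were left out of the comparisons, and some of them carried a rhythm. In a 24 h fit of all 28815 probe sets, 354 of the 7035 without a single symbol were called by limma (5.03%), against 2844 of 21780 with 1 symbol (13.1%). Of the 354, 62 had at least 1.5-fold, and the largest fold was 3.46. Their peaks lay in the subjective night for 55.6%, against 41.6% of the called probe sets with 1 symbol. The difference was not tested, and the genes behind these probe sets were not analysed here. Single values were not tested as outlying within time points of 3 arrays.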

How the results depend on the processing

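The alternatives named here as added were chosen after seeing the data. Leaving out 1 array or time point gave 1978 to 2877 24 h rhythmic genes, a night share of 37.4% to 48.9% and 15 to 17 enriched lists. The other results were refitted without 1 array only. This gave 1824 to 2562 time-dependent genes, 47 to 188 with a 12 h component and 41 to 47 list shifts. The contrasts had 400 to 739 genes for CT12 against CT00, 535 to 1012 for CT15 against CT03, 475 to 1032 for CT18 against CT06 and 420 to 785 for CT21 against CT09. A minimum of 1.5-fold, which removes small changes by construction, left 423 rhythmic, 659 time-dependent and 11 12 h genes, 219, 198, 172 and 182 genes in the contrasts in the order above, a night share of 52.0% and 3 concentrated lists instead of 6. Brighter probe sets (added) gave 1034 rhythmic genes among 2581 tested, so lower counts by construction. This was 40.1% against 13.8% of all genes and so a higher background for the lists. There were 833 time-dependent genes, 322, 341, 430 and 332 in the contrasts, 5 enriched lists and 12 list shifts. Neither clock gene list kept the 3 members needed for a list test there. Bile acid (adjusted p = 0.07), gluconeogenesis (0.1585), autophagy (0.1585), ribosome biogenesis (0.706) and NAD metabolism (0.44) were not enriched. Neither were xenobiotic (0.938), acute phase (0.544), growth hormone (0.747), fatty acid oxidation and glucocorticoid-responsive genes, the last with 1 called member. The shifts of glucocorticoid-responsive genes (CT15 against CT03) and ribosome biogenesis (CT18 against CT06) changed sign without passing. Their signed -log10 p were -0.0402 and -0.14 instead of 3.40 and 4.87. Array weights gave 4900 time-dependent genes, 1388 for CT12 against CT00 and 1211 for CT21 against CT09. The spread of the 6 arrays alone gave 353, 367 and 300 genes for the later 3 contrasts. The 12 h count was 64 with quantile normalization, 50 without moderation and 189 with the small nucleolar RNA covariate (added). The night share was 44.3% with quantile normalization and 36.7% without the 4 farthest arrays (added), where CT15 against CT03 had 440 genes. It was 44.2% with a period of 23 h, where night starts at the middle of that period. By the highest group mean, which allows only the 8 sampled times, it was 51.1%. These last 2 shares count the night differently by construction. An estimated correlation left 12 list shifts, and lists matched on brightness class (added) 9 enriched lists. The cause was not tested for these changes except where construction is named. All other counts stayed within 1.5 times. Among the named genes, fits without 1 array lost 8 calls of 24 h amplitudes and left 2440 results as they were, against 35 and 205 for 12 h amplitudes and 7 and 953 for contrasts. With the replicate number as a block 2984 genes were rhythmic, 2664 time-dependent and 168 had a 12 h component, and the contrasts had 837, 1074, 1148 and 880 genes, with 16 enriched lists (the acute phase response had an adjusted p of 0.0634), 48 list shifts and a night share of 42.0%. The arrays were not treated as paired, since no label names what a number shares and deviations of same-numbered arrays correlated over 0.1 in only 45 of 84 pairs (from -0.40 to 0.50). Their mean correlation was 0.09, against -0.05 for different numbers, and 14 of 24 arrays correlated best with an array of their own number. The 50th percentile filter and the intensity trend were not run, since centred values hold no level, and signal over background is unknown for the same reason.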

Other observations

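Only the tests by reassignment of the arrays were written down before any related value had been seen. The other tests of the small nucleolar RNA level, the 12 h component and the night share were chosen after such values were known, although quantile normalization and the fits without 1 array had been planned as alternatives. The covariate and the restriction to brighter probe sets had not.

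Chance assignment of the arrays to times can be excluded for the 3 counts over the whole cycle, where the alternative is no effect of time at all. For the 12 h count the reassignment also breaks up the 24 h rhythm. It therefore cannot say how many genes a 24 h rhythm alone would give. Of 100 assignments of the 24 arrays, the real one included, 1 gave as many 24 h rhythmic genes as the 2758 found (highest other 2), 1 as many time-dependent genes as the 2167 found (highest other 153), and 1 as many genes with a 12 h component as the 115 found (highest other 30). For the contrasts of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 690, 894, 925 and 709 genes and was the 1 largest of the 10 each time, while the highest of the others were 0, 0, 0 and 2.

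Small nucleolar RNAs, which guide the modification of ribosomal RNA and are short, differed between arrays. The mean of 54 such genes ran from -0.212 to 0.264 over the 24 arrays, and its deviations correlated with the second component of the spread within time points (r = 0.928 in size, 15.9% of that spread), a component made from these same values, but little with the larger first one (r = 0.22 in size, 25.7%). Replicate 1 lay above replicate 3 at all 8 times, and the replicate numbers differed (permutation p = 0.0174), so an order of collection or preparation that followed the numbers is a candidate explanation, although the labels name no such batch. Whether circadian time also contributes stays open (permutation p = 0.293), and so does the spread of the array values (Pearson's r = -0.176, permutation p = 0.671, Spearman's rho = -0.0557, permutation p = 0.848, and r = -0.209 without the 2 arrays of most extreme spread).

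The 12 h component may have technical sources or come from the shape of a daily wave. Both fitted 12 h peaks lay above both troughs at an unadjusted p under 0.05 in 37 of the 51 genes without a 24 h call and in 0 of the 64 with one. Choosing the genes by these calls favours this outcome in both sets, so by this test a single 24 h peak of another shape stays open for all 115. The group means of Arntl, Usp2 and Cldn1 had 1 peak and 1 trough over the cycle. Their 24 h amplitudes were 1.19, 1.02 and 0.79, against 12 h amplitudes of 0.37, 0.39 and 0.31. In 56 of the 115 genes the 12 h amplitude was the larger. With the small nucleolar RNA level as a covariate 103 of the 115 genes kept the call, which argues against that level as the common factor. A total of 41 kept it in all 24 fits without 1 array, so that for the other genes a single array could have tipped the call.

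Night peaks were more frequent among rhythmic genes with at least 1.5-fold (52.0%) than among the others (40.3%), a difference of 11.8 percentage points with a jackknife standard error over arrays of 4.55. Among the former, the 3 h bins beside the boundaries of the night were the fullest. They held 63 genes at 0 to 3 h, 58 at 9 to 12 h, 70 at 12 to 15 h and 70 at 21 to 24 h. The difference therefore depends on where the cycle is cut, and it holds for the cut at CT12 and CT24. With the small nucleolar RNA level as a covariate the difference was 9.92 points, more than 2 standard errors of the main fit above 0. No error was computed for the fit with the covariate. Only if that error is of similar size does this argue against the level as the source of the difference. After quantile normalization it was 6.24 points, and among the 2581 genes with brighter probe sets 5.46 points. Both stay above 0 by less than 2 standard errors of the main fit, and neither has an error of its own. The deposited normalization and the dimness of the probe sets therefore cannot be told apart from a difference in the livers. No biological explanation was tested, since the design holds no group that would change the share.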
